A study of Mus musculus with 6 samples.

How the data were processed

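RNA from mouse fetal gonads, taken at E13.5 (embryonic day) and freed of the mesonephros, was measured on 6 Affymetrix MoGene 1.0 ST arrays, 1 array per pool of gonads. Wild-type gonads were hybridised on 3 arrays, each from a pool of 6 gonads, and gonads of genotype Sox9flox/flox; Sf1:creTr/+ on another 3, each from a pool of 12. In this cross a Cre recombinase driven by regulatory sequence of Nr5a1 (also called Sf1) acts on floxed alleles of Sox9, and this group is called the Sox9 mutant. Arrays carry the numbers of the submitters' labels, 1, 2 and 5 for wild type and 3, 4 and 6 for the mutant. The 2 groups share no number, so no pairing was used. The labels give 300 ng of total RNA per array and name no embryo sex, no floxed exons, and no litter or batch.

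The values used were the deposited log2 values of the series table, which the submitters' processing notes name as RMA output; RMA corrects background, normalizes between arrays by quantiles and summarizes probes into probe sets. Other settings of that step, and the software version, are not given in the sources used here. The values ran from 2.45 to 14.49 log2, and the medians of the 6 arrays lay within 0.06 log2 of each other. RMA compresses the differences of probe sets near background, so the folds of genes close to background are understated. Forced equality of the distributions also means that a general change in RNA content per gonad cannot be seen in such values.

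Of 34760 rows in the table, the 6573 whose identifiers lie below the lowest identifier with a gene annotation were left out (18.9%), as the control block of the array. That rule was set once the identifiers had been seen, because they carry no control prefix. Fitted separately with limma, none of those rows passed an adjusted p of 0.05, and 339 had an unadjusted p under 0.05. Among the 28187 probe sets tested, 21640 were annotated to 1 gene, 1321 to several and 5226 to none in the annotation table used here; genes were named only from probe sets with 1. Of the single-gene probe sets 21553 matched the GRCm38.p6 gene table by Entrez identifier, and 0 symbols changed. A gene was represented by its probe set with the highest mean over all 6 arrays, which gave 19937 genes, 954 of them with more than 1 probe set. As a mark of background, the 95th percentile of the means of 1208 olfactory and vomeronasal receptor probe sets was taken, 6.67 log2.

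The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, 4 residual degrees of freedom before moderation), with Benjamini-Hochberg adjustment over the 28187 probe sets and a threshold of 0.05. Errors beside group means are standard deviations over the 3 arrays, and those beside differences are moderated standard errors. Fixed gene lists, 23 in all, were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 22 lists with at least 3 measured genes, and again with the correlation estimated from the data. The number of arrays limits the precision. In simulated data the noise was independent and had each probe set's moderated spread, equal in both groups. There the limma fit of the mutant against wild type covered 28187 probe sets. It recovered 32.8% of 1.5-fold changes, 95.5% of 2-fold changes and 100% of 4-fold changes, and called 13 unchanged probe sets. These rates are averages over randomly drawn probe sets, and genes that vary more between mutant arrays can miss the threshold at larger changes. Of meiotic genes chosen after their values were seen, Sycp1 was 3.59-fold and Prdm9 2.38-fold higher without passing (limma adjusted p = 0.0538 and 0.216).

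The genes named were fixed by rule before the data were examined, as were the tests, the 23 lists and the alternatives. They are Sox9; the 15 genes with the largest increase and the 15 with the largest decrease among those past the threshold with no overlap between groups, predicted genes without an official symbol excepted; and members of the lists, with the 2 to 4 largest called changes as examples or the 2 highest means where none was called. Genes named beyond the largest changes of a list, and genes outside the lists, are marked as chosen after their values were seen. Exceptions are Thbs2, the single riser of its list, and Nr5a1 and the Y-linked genes, whose values the design asked for. Alternatives were a further quantile normalization, a common median, filters on dim probe sets (above the background mark, or the upper part by mean), eBayes with trend and robust, array weights, a hypothetical batch of numbers 5 and 6, leaving out each array, stricter thresholds, other gene summaries, and camera on ranks. After the values were seen, fits without wild type 5 and mutant 4, and without those and mutant 3, were added, as was a fit of numbers 1 to 4 alone. Figures were drawn with matplotlib 3.10.9.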

Results

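The series compared gonads of mouse embryos that carry floxed Sox9 alleles and an Nr5a1-driven Cre with wild-type gonads at E13.5 (embryonic day), when the fetal testis already holds Sertoli cells in cords, steroid-producing Leydig cells and germ cells. The design asks what the loss of SOX9, a transcription factor of Sertoli cells, changes in the gonadal transcriptome at this stage. Each group had 3 arrays. Pools of 6 wild-type gonads were set against pools of 12 mutant gonads, so pool size went with genotype. No group carried the Cre transgene alone or the floxed alleles alone, so effects of either cannot be told from the loss of Sox9. Nothing in the labels says that the pools of a group came from separate litters, and p-values then measure only the spread between these samples, which may be partly technical. Correlations across all probe sets were 0.984 to 0.992 between arrays of a group and 0.969 to 0.985 between groups, and the first principal component, with 48.9% of the variance, separated the groups. The second, with 23.3%, set wild type 5 and mutant 6 apart from the 4 other arrays, a difference in both groups for which the labels name no batch.

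Sox9 itself measured 8.82, 8.81 and 9.20 log2 on wild-type arrays 1, 2 and 5, and 7.52, 7.78 and 7.60 on mutant arrays 3, 4 and 6. It fell by 1.31 ± 0.14 log2 (SE; limma adjusted p = 0.00124), a 2.48-fold difference, and the mutant arrays stayed above the background mark of 6.67 log2. The labels do not give the floxed exons, so whether the probe set reads the deleted part is not known here. Nr5a1, whose regulatory sequence drives Cre, measured 10.44 ± 0.14 log2 in wild type and 10.42 ± 0.22 in the mutant (SD, n = 3 each; adjusted p = 0.971), a difference that changed sign between scalings. Of 7 measured genes at the Nr5a1 locus, Nr6a1 rose by 1.51 log2 and 6 did not pass. The list's median was -0.02 and its mean 0.15, so these differ in sign (camera adjusted p = 0.752). Adjusted over the list alone, the same count of 1 rose. Among 20 genes around Sox9, Abca5 rose by 0.77 log2 while Cpsf4l fell by 0.63 and Cog1 fell by 0.58, and 17 did not pass (adjusted p = 0.980). Adjusted over this list alone, 4 rose and 5 fell. Calls of Cpsf4l and Cog1 were lost with single arrays left out, wild type 1 or 5 or mutant 3 or 4 for Cpsf4l (adjusted p up to 0.111) and any but mutant 4 for Cog1 (up to 0.102), and that of Abca5 without wild type 5 and mutant 4 together (adjusted p = 0.0792).

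In all, 1384 of 19937 genes passed the threshold, 527 higher and 857 lower in the mutant, and 145 and 215 of these changed at least 2-fold. By probe set, 630 were higher and 981 lower of 28187. The 1384 genes had no overlap between the 3 mutant and 3 wild-type values; 28.7% of all genes had none, against 10% by chance. Both group means of 90 called genes lay below the background mark, and 1 mean of another 175. The largest increases were in Meioc, Fst, Stra8, Lrrn1, Taf7l, M1ap, Chrm4, Meiob, Rec8, Lrrc34, Phlda2, Bhlhe41, Mbnl3, Sycp3 and Tnfrsf19, from 4.11 to 2.31 log2. The largest decreases were in Cyp11a1, Amh, Cyp17a1, Cst9, Adh1, Hsd17b3, Star, Cbln1, Aard, Hhip, Ephx1, Defb19, Gstm6, Tmem184a and Lefty2, from -4.70 to -2.37 log2. Leaving out 1 array reduced the genes called to 593 without wild type 1, 721 without wild type 2, 778 without wild type 5, 689 without mutant 3 and 904 without mutant 4, with 1292 without mutant 6. With numbers 5 and 6 as a batch term, 820 genes were higher and 1241 lower, and among numbers 1 to 4 alone, 382 and 513. Numbers 5 and 6 hold 1 array per group and allow no test of their own. Their list medians were -1.57 (Sertoli), -1.86 (Leydig) and 1.09 log2 (pregranulosa), against -1.27, -1.47 and 1.21 within numbers 1 to 4. Calls among these genes that an alternative ended were those of Taf7l (adjusted p up to 0.134), Meiob (0.154), M1ap (0.064), Sycp3 (0.116), Cyp11a1 (0.0969), Amh (0.0802), Cyp17a1 (0.150), Hsd17b3 (0.0518), Cbln1 (0.0557) and Lefty2 (0.0767), each with eBayes with trend and robust among the settings that ended it. Single arrays ended those of Taf7l (wild type 1 or 5, mutant 3 or 4), Meiob (wild type 1, 2 or 5, mutant 4), Cyp17a1 (wild type 1, 2 or 5, mutant 3) and Lefty2 (wild type 1 or 5, mutant 3).

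**Figure D1:**
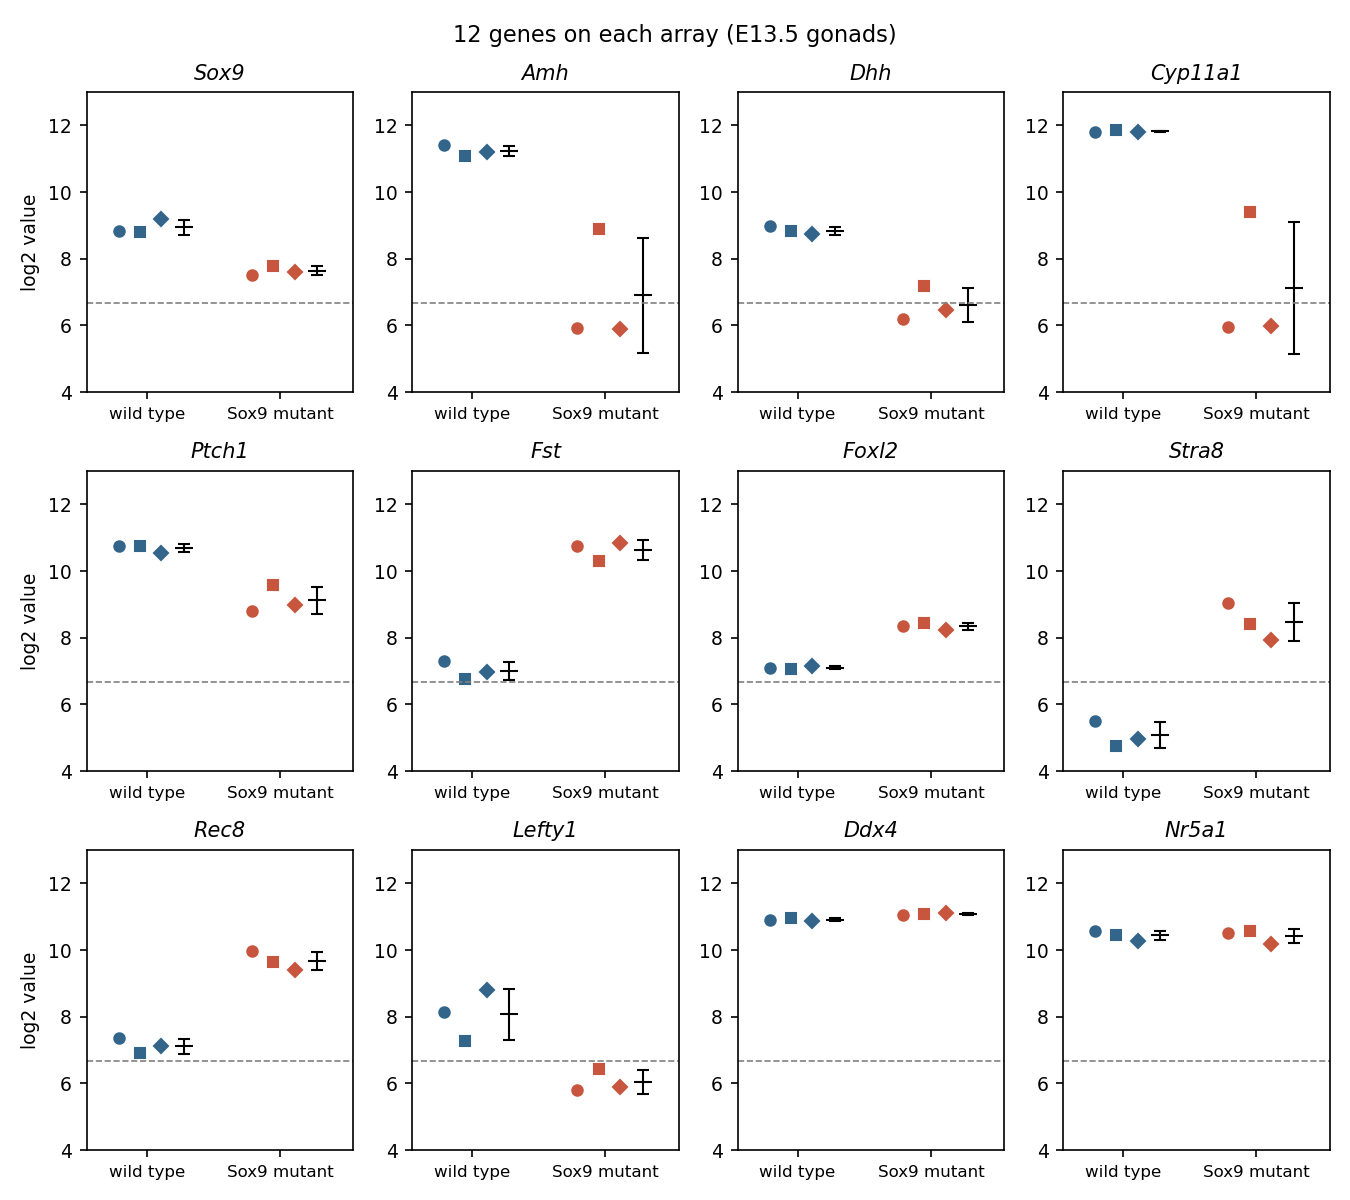
Log2 value of 12 genes on each array; circles, squares and diamonds are replicates 1, 2 and 5 of wild type (blue) and 3, 4 and 6 of the Sox9 mutant (red), bars are mean ± SD (n = 3) and the dashed line is the background mark. Sox9 lay at 8.81 to 9.20 in wild type and 7.52 to 7.78 in the mutant, and mutant 4 stood above mutants 3 and 6 for Amh and Cyp11a1.

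Genes of Sertoli cells were lower in the mutant. Amh, the hormone that makes the Müllerian ducts regress, fell from 11.23 ± 0.16 to 6.90 ± 1.74 log2 (SD, n = 3 each), a 20.1-fold difference. Its values on mutants 3, 4 and 6 were 5.91, 8.91 and 5.89. Those of mutants 3 and 6 lay below the background mark, where the size of a fall is limited. Cst9 fell by 4.14 log2, Hsd17b3, which makes testosterone from androstenedione, fell by 3.51 and Aard fell by 2.94. Of list members chosen after their values were seen, Dhh, the Hedgehog ligand secreted by Sertoli cells, fell by 2.24 and Ptgds, a prostaglandin D synthase, fell by 2.02. Of 26 measured list members 19 fell, 0 rose and 7 did not pass, and adjusted over the list alone 23 fell (median -1.35 log2, camera adjusted p = 2.38e-24). With an estimated correlation the list gave adjusted p = 0.204, the highest of its alternatives. Sox10, also chosen after its values were seen, with a difference of -0.48 log2 (limma adjusted p = 0.115), was among those that did not pass. With numbers 5 and 6 as a batch Sox10 passed (limma adjusted p = 0.0407), and 21 list members fell. Sertoli members fell less on mutant 4 than on mutants 3 and 6, with medians of -1.05, -1.50 and -1.54 log2 against the wild-type mean.

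Leydig cell and steroid synthesis genes fell too. Cyp11a1, which starts steroid synthesis from cholesterol, fell from 11.82 ± 0.03 to 7.12 ± 1.99 log2 (SD, n = 3 each). It measured 5.96, 9.41 and 5.98 on mutants 3, 4 and 6, below the background mark on mutants 3 and 6. Cyp17a1 fell by 4.29 log2, Star, which carries cholesterol into mitochondria, fell by 3.34 and Hsd3b1 fell by 2.34. Of 11 measured genes of this list 8 fell, Thbs2, which encodes a matrix glycoprotein, rose by 1.98 and 2 did not pass. Adjusted over the Leydig list alone 9 fell and 1 rose (median -1.60, adjusted p = 3.03e-08, and adjusted p = 0.194 with an estimated correlation). Each of the 3 measured Hedgehog targets fell, with differences of -2.74 (Hhip), -1.56 (Ptch1) and -1.24 log2 (Gli1), the same 3 adjusted over the list alone (adjusted p = 2.54e-05, and adjusted p = 0.204 with an estimated correlation). Cholesterol synthesis enzymes fell by less, with differences of -1.13 (Cyp51), -1.10 (Msmo1), -0.97 (Lss) and -0.90 log2 (Nsdhl). In that list 12 of 14 measured genes fell and 2 did not pass, 13 falling adjusted over the list alone (median -0.64, adjusted p = 9.47e-13, and adjusted p = 0.204 with an estimated correlation). The count of 12 was 5 without wild type 1, 4 without wild type 2, 6 without wild type 5 or mutant 3, 8 without mutant 4 and 11 without mutant 6, and 3 without wild type 5 and mutant 4 together. On mutant 4 the Leydig median was -1.28 log2, against -1.69 and -1.83 on mutants 3 and 6. Over the alternatives the adjusted p of Cyp17a1 ran from 2.80e-08 to 0.150 and that of Cyp11a1 from 2.80e-08 to 0.0969. The call of Nsdhl ended without wild type 5 and mutant 4 (adjusted p = 0.0538).

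**Figure D2:**
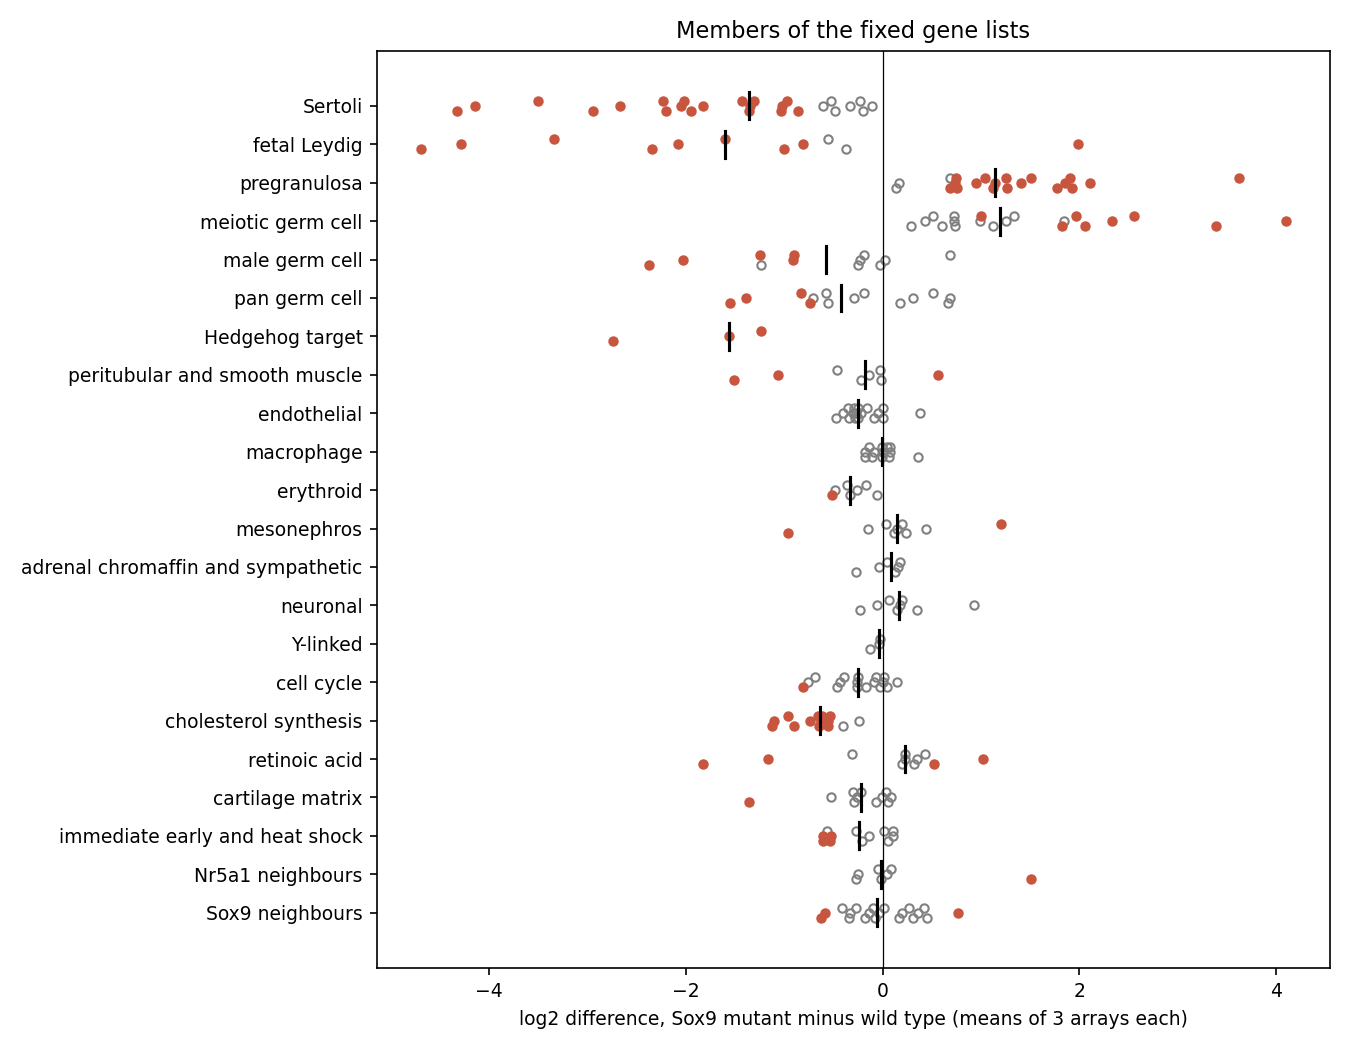
Log2 difference between the means of 3 mutant and 3 wild-type arrays for each measured member of 22 fixed gene lists; filled points passed an adjusted p of 0.05, open points did not, and the bar is the list's median. Sertoli members have a median of -1.35 and pregranulosa members of 1.14.

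Genes of pregranulosa cells, the supporting cells of the fetal ovary, were higher in the mutant. Fst, which binds activin, rose from 7.01 ± 0.27 to 10.63 ± 0.29 log2 (SD, n = 3 each), 12.3-fold, Bmp2 by 2.11, Runx1 by 1.93 and Irx3 by 1.90 log2. Among members chosen after their values were seen, Foxl2, a transcription factor of the ovarian supporting cells, rose by 1.25, Rspo1, a WNT pathway activator, by 1.41 and Wnt4 by 1.12. In total 18 of 21 rose, 0 fell and 3 did not pass, 19 rising adjusted over the list alone (median 1.14, camera adjusted p = 1.36e-26). With an estimated correlation its adjusted p = 0.0652. The genes named here passed in each alternative in which they were measured.

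Meiotic genes of germ cells were higher, and 5 of 12 male germ cell genes were lower. Meioc rose from 5.36 ± 0.65 to 9.46 ± 0.99 log2 and Stra8, needed for entry into meiosis, from 5.07 ± 0.39 to 8.47 ± 0.57 (SD, n = 3 each). Both wild-type means lay below background, so these folds of 17.2 and 10.5 are understated. Rec8, a meiotic cohesin, rose by 2.55 and Sycp3, of the synaptonemal complex, by 2.34 log2. Of 20 list members 8 rose and 12 did not pass, 13 rising adjusted over the list alone (median 1.19, adjusted p = 5.68e-14, and adjusted p = 0.262 with an estimated correlation). The count of 8 was 5 without wild type 1 or 5, 6 without wild type 2, mutant 3 or mutant 4, and 13 without mutant 6. It was 5 with trend and robust, and 11 with array weights, the batch term or the mean of each gene's probe sets. Hormad1, chosen after its values were seen, did not pass at its brighter probe set (0.74 log2, limma adjusted p = 0.229). Its other probe set rose by 1.77 log2 (adjusted p = 0.0041). The list's median differed between mutant arrays, 2.22 on mutant 3, 1.31 on mutant 4 and 0.34 on mutant 6. The mutant exceeded wild type by a median of 1.62 within numbers 1 to 4 and 0.74 within 5 and 6. Among 12 male germ cell genes 5 fell and 7 did not pass, with 6 falling and 1 rising adjusted over the list alone. Those 7, named after their values were seen, were Nanos2 (-1.24), Dnmt3l (-0.25), Tdrd1 (-0.23), Piwil4 (-0.19), Piwil2 (-0.02), Tdrd9 (0.02) and Mov10l1 (0.69 log2). The called falls of this list were -2.37 (Lefty2), -2.03 (Lefty1), -1.25 (Tdrd5) and -0.91 log2 (Nodal) among others (median -0.58, adjusted p = 0.000514, and adjusted p = 0.204 with an estimated correlation). Its count of 5 was 1 without wild type 1 and 3 without mutant 3. That list's call also ended among the brighter probe sets alone (adjusted p = 0.492), and those of Tdrd5 (adjusted p = 0.118), Lefty2 (0.0722) and Lefty1 (0.0503) without wild type 1. Tdrd5 also lost its call without wild type 2, mutant 3 or mutant 6 or with trend and robust, and Lefty2 without wild type 5 or mutant 3 or with trend and robust (0.0767).

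General germ cell genes split. Of 2 members chosen after their values were seen, Ddx4 measured 10.91 ± 0.04 log2 in wild type and 11.09 ± 0.03 in the mutant (adjusted p = 0.409), and Dazl 11.35 ± 0.15 and 11.66 ± 0.03 (adjusted p = 0.183; SD, n = 3 each). Dppa3, Utf1, Dnd1 and Prdm1, genes of undifferentiated germ cells, fell (differences of -1.55, -1.39, -0.83 and -0.74 log2), while 10 of 14 did not pass. Adjusted over this list alone 7 fell and 3 rose (adjusted p = 0.103). Each of these 4 calls was lost without wild type 1, 2 or 5, with adjusted p up to 0.0815 for Dppa3, 0.110 for Utf1, 0.167 for Dnd1 and 0.0618 for Prdm1. Those of Dnd1 and Prdm1 were lost without mutant 3 or 4 too, that of Dnd1 with quantile normalization (adjusted p = 0.0611), and those of Dppa3 and Utf1 with trend and robust (0.0573 and 0.0705). Without mutant 3, 1 member rose. Without mutant 6 the list passed (adjusted p = 0.0142).

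**Figure D3:**
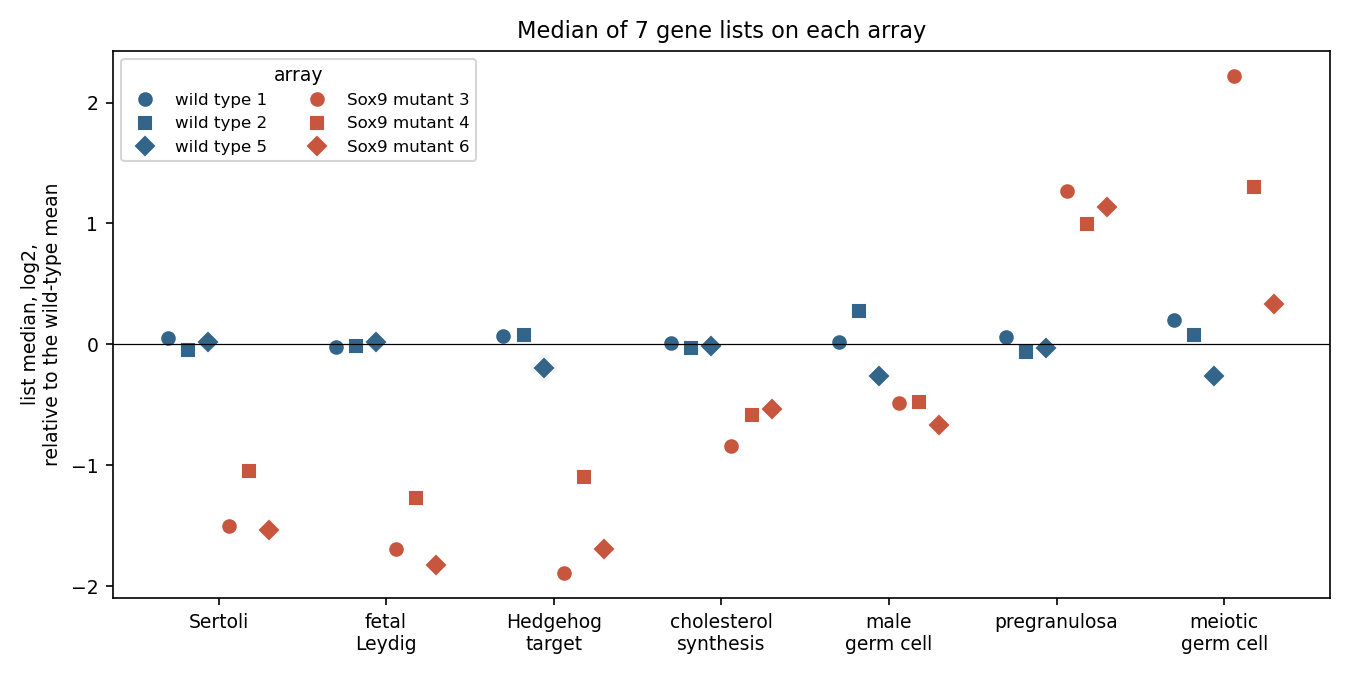
Median log2 difference from the wild-type mean of 7 gene lists on each array; blue marks are wild type and red marks Sox9 mutant arrays. The Sertoli and Leydig medians of mutant 4, at -1.05 and -1.28, lie nearer 0 than those of mutants 3 and 6.

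Further lists covered other cell types of the gonad and its surroundings. For comparison with the counts below, 4324 of all 19937 genes had an unadjusted p under 0.05 in the limma fit. Of 8 smooth muscle and peritubular genes Acta2 fell by 1.51 and Tagln fell by 1.07, Myh11 rose by 0.56 log2 and 5 did not pass, with 3 falling and 1 rising adjusted over the list alone (adjusted p = 0.0861, and 0.0472 without wild type 1). None of 17 endothelial genes passed in the limma fit, with or without adjustment over the list alone (7 had an unadjusted p under 0.05), although their list was lower (median -0.25, adjusted p = 0.0123, and adjusted p = 0.339 with an estimated correlation). With array weights, and with either filter on dim probe sets, 1 endothelial gene fell. Kdr measured 9.40 and 9.78 log2 and Cdh5 9.34 and 9.06 in wild type and mutant. No macrophage gene of 13 passed either way (1 with an unadjusted p under 0.05, camera adjusted p = 0.980), with Csf1r at 7.37 and 7.38 log2. Both group means of 6 macrophage genes lay below the background mark. In the erythroid list 1 of 7 measured genes, Alas2, fell by 0.51 log2, also alone (adjusted p = 0.0506). Wild type 5 stood highest of the 6 arrays there, and without it the list's adjusted p was 0.319, against 0.00840 without wild type 1 and 0.0181 without mutant 6. On wild type 5 the liver genes Afp and Alb, chosen after their values were seen, measured 11.26 and 11.42 log2, against means of 5.71 and 6.00 on wild type 1 and 2. Of 9 mesonephric genes Gata3 rose by 1.20 and Lhx1 fell by 0.96 log2, 2 rising and 1 falling adjusted over the list alone (adjusted p = 0.134). No chromaffin gene of 6 (camera adjusted p = 0.836) and no neuronal gene of 8 (adjusted p = 0.139) passed, alone included, with 1 and 2 at an unadjusted p under 0.05. Both group means of 4 chromaffin and 6 neuronal genes lay below the background mark, so these lists say little about such cells. Without mutant 6, with numbers 5 and 6 as a batch or among numbers 1 to 4 alone, 1 neuronal gene rose. The neuronal list passed among numbers 1 to 4 alone (adjusted p = 0.0394). The call of Alas2 and Myh11 ended without any 1 array, that of Tagln without wild type 1 and that of Lhx1 without wild type 1, wild type 2 or mutant 3, with adjusted p up to 0.121, 0.135, 0.0540 and 0.0835.

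Lists of retinoic acid, cartilage, cell cycle and handling genes moved in part. In the retinoic acid list Cyp26b1, the enzyme that degrades retinoic acid and also a Sertoli list member, fell by 1.83 and Aldh1a1 fell by 1.17, while Crabp1 rose by 1.02 and Aldh1a2 by 0.52 log2. Adjusted over that list alone 4 of 11 rose and 3 fell. Its median was 0.22, its mean -0.003 and its test upward (adjusted p = 0.183), so the mean differs in sign. Of 11 cartilage matrix genes Col9a3, also in the Sertoli list, fell by 1.36 log2, with 2 falling adjusted over the list alone (adjusted p = 0.0373, and adjusted p = 0.217 with an estimated correlation). In simulated data with only the Sertoli list shifted, by -1 log2, camera at the preset correlation called 3 lists. With nothing shifted it called 0 of 22. Col9a3, and Cyp26b1 of the retinoic acid list, are Sertoli members and were shifted too. The other calls may thus rest on shared members, and do not show that a list without them would be called. Among 17 cell cycle genes Aurkb fell by 0.81 log2, with 3 falling adjusted over the list alone (adjusted p = 0.00921, adjusted p = 0.0729 without mutant 3, and adjusted p = 0.488 with an estimated correlation). Immediate early and heat shock genes, which respond to tissue handling, had 4 of 12 lower, with differences of -0.61 (Hspa1a and Ier2), -0.54 (Jun) and -0.52 log2 (Dnajb1), and 5 adjusted over the list alone (adjusted p = 0.0123, and adjusted p = 0.251 with an estimated correlation). The calls of Aldh1a2 and Jun ended without any 1 array (adjusted p up to 0.121 and 0.157), and those of Crabp1 (0.0565), Aurkb (0.0731), Hspa1a (0.0588), Ier2 (0.106) and Dnajb1 (0.0709) without wild type 1. Without mutant 6, 3 cell cycle genes fell. Aurkb lost its call also without wild type 5 or mutant 3, Hspa1a without mutant 4, Ier2 without any but mutant 4 and Dnajb1 without any but mutant 6. The cartilage call ended without wild type 2 (0.0514), wild type 5 (0.0576) or mutant 4 (0.0693).

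No label gives the sex of the embryos. Of 3 measured Y-linked genes none passed in the limma fit, alone included, and 0 had an unadjusted p under 0.05. Eif2s3y measured 9.70 ± 0.12 and 9.66 ± 0.07 log2 in wild type and mutant, Uty 8.44 ± 0.10 and 8.41 ± 0.42, and Kdm5d 8.27 ± 0.13 and 8.14 ± 0.28 (SD, n = 3 each; camera adjusted p = 0.824). Xist measured 5.42 ± 0.07 log2 in wild type and 5.75 ± 1.33 in the mutant (adjusted p = 0.802), with 7.29 on mutant 3 against 5.0 and 4.97 on mutants 4 and 6. All but the value of mutant 3 lay below the background mark.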

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

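The fits without wild type 5 and mutant 4, and without those and mutant 3 (which leaves 1 mutant array, assumed to vary like the others), and that of numbers 1 to 4 alone were chosen after the values were seen; the rest were planned. No list called with all 6 arrays and the planned choices changed direction in any setting, and neither did any of the 84 called genes that were followed. For those genes this was fixed in advance where arrays were left out or weighted or a batch term was added. The called genes had no overlap between the groups, so such settings cannot turn them. Sox9 passed in each setting with more than 1 array per group (limma adjusted p up to 0.00855). Of the 84 called genes that were followed, 52 passed in every setting that measured them. The cause of the changes below was not tested unless fewer arrays, fewer probe sets or a stricter threshold made them. With numbers 5 and 6 as a batch, 1059 probe sets and 820 genes were higher. At 2-fold or more, 178 probe sets were higher and 257 lower (genes 145 and 215), and at an adjusted p under 0.01, 233 and 367 (genes 199 and 328). Leaving out 1 array gave 312 to 697 probe sets higher and 372 to 867 lower, and 262 to 546 genes higher and 330 to 746 lower. Without wild type 5 and mutant 4, 237 probe sets were higher and 474 lower (genes 199 and 405). Among numbers 1 to 4 alone, 612 probe sets and 513 genes were lower, and the pan germ cell (adjusted p = 0.0138) and neuronal lists (0.0394) passed. With an estimated correlation no list was called (5 had an unadjusted p under 0.05), with adjusted p of 0.0652 (pregranulosa), 0.194 (Leydig), 0.204 (Sertoli, male germ cell, Hedgehog, cholesterol), 0.217 (cartilage), 0.251 (immediate early), 0.262 (meiotic), 0.339 (endothelial) and 0.488 (cell cycle). Above the background mark the calls of the endothelial (adjusted p = 0.0788), cell cycle (0.0692) and immediate early lists (0.0839) ended, and in the upper part by mean those of the male germ cell (0.492), endothelial (0.117), cell cycle (0.117) and cartilage lists (0.0567). On ranks the cartilage list gave 0.0542. The erythroid list passed with quantile normalization (0.0489), the batch term (0.0393) and ranks (0.0277), and turned upward, without a call, in the second added fit (0.937). Without wild type 5 and mutant 4, cartilage gave 0.101 and immediate early 0.0770; with mutant 3 also out, cartilage and immediate early gave 0.217, endothelial 0.487, cell cycle 0.764 and smooth muscle, now called, 0.0117. With 1 array left out the adjusted p ran from 0.0142 to 0.140 for the pan germ cell list, 0.0472 to 0.148 for smooth muscle, 0.00840 to 0.319 for erythroid, 0.000763 to 0.0729 for cell cycle and 0.0265 to 0.0693 for cartilage. Results called in no setting changed sign as follows. The macrophage list turned upward above the background mark (0.821), in the upper part (0.696), with trend and robust (0.972), among numbers 1 to 4 (0.672), without wild type 5 and mutant 4 (0.404) and with mutant 3 also out (0.654), with 0.639 to 0.928 over single arrays. The chromaffin list turned downward with quantile normalization (0.95) and in the added fits (0.895 and 0.607; 0.407 to 0.978 over single arrays). The Y-linked list turned upward with quantile normalization (0.999) and in the second added fit (0.607; 0.262 to 0.935). The Nr5a1 neighbours turned on ranks (0.912) and in the added fits (0.895 and 0.764; 0.343 to 0.979) and the Sox9 neighbours with a common median (0.992) and the batch term (0.973; 0.890 to 0.928 over single arrays). Log2 differences turned for Csf1r with quantile normalization (-0.00155), a common median (-0.0176) and the first added fit (-0.0146), for Nr5a1 with quantile normalization (0.056), array weights (0.0222) and numbers 1 to 4 alone (0.0317), for Eif2s3y with quantile normalization (0.0184), for Uty with quantile normalization (0.0203) and the added fits (0.0293 and 0.45), for Cx3cr1 in the added fits (0.23, 0.30 and, in numbers 1 to 4, 0.0305), and in the second added fit for Xist (-0.44) and Kdm5d (0.14). Single arrays gave -0.15 to 0.12 for Cx3cr1, -0.0400 to 0.032 for Csf1r, -0.0813 to 0.15 for Chga, -0.024 to 0.15 for Stmn3, -0.25 to 0.17 for Uty, -0.44 to 0.72 for Xist and -0.0938 to 0.11 for Nr5a1. Folds of genes near background, below 6.67 log2, are limited by the signal of the arrays.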

Other observations

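Further gene groups were put together after the values were seen, and some of their members (Fst, Bmp2, Nr5a1, Amh, Inhbb and all of the undifferentiated germ cell group) also stand in the fixed lists. Of 8 gonadal transcription factor genes 4 rose and 4 did not pass: Gata2 rose by 1.88 and Emx2 by 1.61 log2, and Sry, the testis-determining gene, rose from 7.50 ± 0.18 to 8.18 ± 0.13 log2 (SD, n = 3 each; limma adjusted p = 0.0181, and up to 0.0879 without wild type 1, wild type 2 or mutant 4). Of 6 measured genes of interstitial progenitors 5 fell, with differences of -1.22 for Tcf21, -1.16 for Pdgfrb, -0.97 for Vcam1 and -0.81 log2 for Pdgfra. Among 11 genes of BMP, activin and AMH signalling 3 rose and 5 fell: Inha fell by 2.25, Inhba fell by 1.75 and Bmp4 fell by 1.09 log2, while Bmp2 and Fst rose. Of 6 genes of undifferentiated germ cells 3 fell and 3 did not pass.

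The tests below were chosen after the patterns were seen, except that of other splits of the arrays. The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 1611 probe sets, and 1 split, the real one, gave as many, while the highest of the others gave 0 by limma. Every other split put both genotypes into each group, so the difference between genotypes entered the residual spread. The 0 calls there therefore say nothing about chance. At an unadjusted p under 0.05 the real split gave 5426, and of the others the one that sets wild type 5 and mutant 6 apart, with wild type 1, gave the most, 2878.

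On mutant 4, genes that fell in the mutant stood between wild type and mutants 3 and 6, as with Amh at 8.91 against 5.91 and 5.89 log2. Over 249 genes that fell in a fit without mutant 4, its median fraction of the way to wild type on the linear scale was 0.204, which argues against a wild-type array in its place, since that needs about 1. Over 137 genes that rose the fraction was 0.245, inside the range between quartiles of the fallen genes (0.143 to 0.265), and consistent with tissue of wild-type profile in that pool; the same procedure gave -0.0938 and 0.0104 for mutant 3 and -0.0763 and 0.0453 for mutant 6. Incomplete loss of Sox9 within these gonads stays open: the fraction at Sox9 itself was 0.103, which an admixture raises as well. Without wild type 5 and mutant 4 together, 604 genes passed.

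On wild type 5, liver genes were high: Afp measured 11.26 log2 against a mean of 5.71 on wild type 1 and 2, and Alb 11.42 against 6.00. The median of 22 other hepatic genes listed after Afp, Alb, Serpina6 and Apoa1 had been seen was 1.38 log2 higher on wild type 5, 18 of them by 0.5 or more, and none of 10000 random lists matched on mean level reached it (highest 0.30). Of the 22, 7 lay above the background mark on wild type 1 and 2. This median lay 1.08 log2 above the highest random list. That distance cannot decide about a shift of the whole array, because quantile normalization takes such shifts out before the lists are drawn. The random lists also drew genes without regard to whether they vary together. Fetal liver tissue in that pool may account for the values of the liver genes, and without wild type 5, 778 genes passed.

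Meiotic genes differed among mutant arrays: all 20 were higher on mutant 3 than on mutant 6, by a median of 1.28 log2, and all 20 on mutant 4 than on 6, by 0.54. Different germ cell numbers are argued against by Ddx4 and Dazl alone, with a mean difference of -0.022 log2 between mutants 3 and 6. Both belong to the pan germ cell list of 14 genes, whose other members differed more and in both directions. That list's median was -0.81 log2 on mutant 3 and -0.22 on mutant 6, while Mael was higher on mutant 3 (10.17 against 9.17). Numbers 5 and 6, which the second principal component set apart, were low in both groups: 18 of the 20 genes were lower on wild type 5 than the mean of wild type 1 and 2, with a median of -0.40 log2 against a lowest value of -0.26 in 10000 random lists matched on mean level. The low values of mutant 6 may thus belong to a difference shared by numbers 5 and 6. Such a difference leaves out the contrast of mutants 3 and 4, where all 20 were higher on mutant 3, by a median of 0.76 log2 (highest random list 0.21). The random lists drew unrelated genes, while the meiotic genes varied together, with an estimated correlation of 0.831. Lying outside the random lists therefore does not measure how unusual either median is. XX gonads, whose germ cells enter meiosis at this stage, stay open: Xist differed by 0.0291 log2 between mutants 4 and 6, but both readings lie below the background mark and decide nothing, and on mutant 3 Xist above that mark came with a median difference of -0.24 log2 in Y-linked genes, within their spread of 0.49 between mutants 4 and 6. Germ cells further advanced in the pool of mutant 3 stay open as well: all 6 genes of undifferentiated germ cells were lower there than on mutants 4 and 6 (median -0.91 log2 against their mean), but XX germ cells could give the same values, and no test here separates the 2. Between mutants 4 and 6 this was not decided, with 5 of the 6 lower on mutant 4 and a median of -0.26 log2.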
